A study of Mus musculus with 18 samples.

How the data were processed

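Expression was profiled with Affymetrix mouse exon arrays in 18 samples, 3 for each of 6 groups: normal GMP and MLL-AF9 GMP-like cells, each with an EPC1 knockdown vector, an EPC2 knockdown vector or a non-targeting control. Per the labels, cells were purified by flow sorting from C57BL/6 mice, infected by spinoculation for 30 minutes and cultured for 42 hours with SCF, IL3, IL6 and GM-CSF, and RNA came from successfully infected cells. Replicates were separate animals for normal GMP and separate leukaemias for the MLL-AF9 cells. Whether the same number in different groups meant the same animal was not given in the sources used here. RNA was amplified with a whole-transcriptome kit from 1 ng in 6 samples and 40 ng in the others. The sample numbers of that protocol were read as following the order of the titles, which makes the 1 ng samples replicate 1 of each group; this reading is an inference.

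The deposited values are log2 intensities per probeset, and a second deposited table holds log2 values per Ensembl gene. The submitters' processing notes name RMA as the only step, and its version and settings were not given in the sources used here. The base of the logarithm was taken as 2, the base of RMA output. The probeset table held 267824 probesets, of which 242247 had 1 gene symbol in the array's probe table, 2077 had several and 23500 had none. Only probesets with 1 symbol were used. The 18957 symbols became 18916 after 3003 were replaced through synonyms, and 18868 were current RefSeq symbols (names from assembly GRCm38.p6; no coordinates were used). No table given here paired the Ensembl identifiers of the 23770 gene-level values with symbols. The values per gene were therefore the mean of the probesets of a symbol (median 10 probesets), and the gene-level table served as an alternative for counts. For 7357 symbols this mean matched a gene-level value within 0.001 log2 (root mean square). No 2 arrays held identical values.

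Genes with a mean log2 value over all 18 arrays at or above the 40th percentile (5.45) were tested, with Epc1 and Epc2 always kept, which left 11350. Group means were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 18 arrays, so that all groups shared 1 estimate of the spread (12 residual degrees of freedom). Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Of the comparisons, 9 were planned before the data were examined, together with the threshold, the lists and the rule for named genes, and 2 were added later, the mean effects of each vector over both cell types. Named genes were up to 10 per direction with the largest change among called genes whose groups did not overlap, then genes called by the fit with replicate number as a block, then up to 3 with the smallest p, given as values. Over both cell types, a gene qualified when all 6 pairs moved the same way. Epc1, Epc2 and Myc were named in every comparison, and up to 4 called members of each list. Prep and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

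Replicate number pairs the arrays by a rule set before the fits were compared: the deviations of same-numbered arrays from their group means correlated above 0.1 in all 18 pairs within a cell type, at 0.228 to 0.689 in normal GMP and 0.547 to 0.920 in leukaemic GMP. The pairing comes from the data, not from the labels, and replicate 1 drives it. Deviations within a group sum to 0, so a shift shared by the replicate 1 arrays alone also raises the same-numbered correlations of replicates 2 and 3. The rule could therefore hardly fail. Of 9 arrays per cell type, 8 in normal GMP and 3 in leukaemic GMP correlated best with an array of their own number. Replicates 2 and 3 of leukaemic GMP were thus not shown to be paired by number. The difference of replicate 2 minus replicate 3 correlated between groups at 0.139 to 0.190 in normal GMP, but at 0.0164, -0.255 and -0.343 in leukaemic GMP. Between the control arrays of the cell types, which are separate animals and leukaemias, same-numbered deviations correlated at 0.381, 0.309 and 0.210 for replicates 1, 2 and 3, and replicate 2 minus 3 at -0.0111. With replicate number as a block within each cell type (8 residual degrees of freedom; blocks across cell types for the control comparison), limma called 52 genes for EPC2 over both cell types against 0 without.

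The 30 gene lists, fixed beforehand, held 987 members, 856 of them measured, and lists with fewer than 5 tested members would not have been tested. They covered the NuA4/TIP60 complex, Polycomb group, MYC targets, MYC network, MLL fusion targets, stem cell genes, p53 targets, apoptosis regulators and proliferation brakes. Cell cycle and metabolism lists covered G1/S, G2 and M phase, histones, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, autophagy and lysosome, and stress and unfolded protein response. The others covered interferon response, immediate early and NF-kB genes, and markers of neutrophils, primary granules, monocytes, dendritic cells, eosinophils, mast cells and basophils, erythroid cells, megakaryocytes and lymphocytes. Lists were tested with limma's camera at its preset correlation, which compares a list with all other genes, with camera at an estimated correlation and with fry as alternatives, and adjusted over the lists of a comparison. Some lists share members, for example 4 between p53 targets and apoptosis regulators.

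Single target genes were compared with exact permutation tests. Other alternatives were no filter, a stricter filter (60th percentile, 7567 genes), RNA input as a covariate, only the arrays compared, an intensity trend with a robust prior, quantile normalization, the gene-level table and leaving out each array. Added after seeing the data were a replicate 1 covariate within each cell type, the arrays of replicates 2 and 3 alone and combinations with the block. Correlations between knockdowns were set against 100 simulations of unchanged groups with shared controls.

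On simulated data with 11350 genes, of which 100 were changed per size, the fit for EPC2 in leukaemic GMP recovered 1% of changes of 0.5 log2 and 41% of changes of 1.0 without the block, and 38% and 99% with it, where 10 unchanged genes were also called. For EPC2 over both cell types it recovered 19% and 79% without the block, and 86% and 100% with it, with 11 unchanged genes called. The simulated arrays were built from the blocked fit, with its replicate shifts, its spread and independent noise for each gene. The gain with the block was thus set by the construction and does not show that the block suits the real arrays.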

Results

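Gene expression was measured on 18 mouse exon arrays. Normal granulocyte-macrophage progenitors (GMP), the marrow cells that give rise to neutrophils and monocytes, made up 9 of them. The other 9 held leukaemic GMP-like cells driven by MLL-AF9, a fusion of the MLL gene that causes acute myeloid leukaemia. Within each cell type, 3 arrays came from cells infected with a lentivirus against Epc1, 3 from cells infected against Epc2 and 3 from cells with a non-targeting control (NTC). Epc1 and Epc2 encode Enhancer of Polycomb proteins, subunits of the NuA4/TIP60 histone acetyltransferase complex. Array intensities carry no counts, so the number of arrays limits the precision. Median log2 intensity over all genes with a symbol ranged from 5.75 to 5.97 between arrays. Over the tested genes the spread was wider. It ran from 6.61 in replicate 3 of the leukaemic EPC2 knockdown to 7.20 in replicate 1 of the leukaemic EPC1 knockdown. Values below are log2 intensities and log2 differences, with the SD over 3 arrays for group means and the standard error (SE) for differences.

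Both vectors were followed by a lower mean level of the gene they targeted, in both cell types. In normal GMP, Epc1 was 7.78 ± 0.25 (SD, n = 3) in the control and 7.32 ± 0.23 after EPC1 knockdown, a difference of -0.47 or 72.3% of the control intensity. In leukaemic GMP it was 8.08 ± 0.03 in the control and 7.69 ± 0.02 after EPC1 knockdown, a difference of -0.39 or 76.4% of the control. Epc2 was 7.39 ± 0.25 in the normal control and 6.87 ± 0.75 after EPC2 knockdown, a difference of -0.51 or 70.0% of the control, and the pair of replicate 1 (-1.10) carried much of it, with -0.14 and -0.30 in the other pairs. In leukaemic GMP, Epc2 was 7.32 ± 0.11 in the control and 7.01 ± 0.11 after EPC2 knockdown, a difference of -0.31 or 80.6% of the control, with -0.07, -0.43 and -0.44 in the pairs of replicates 1, 2 and 3. Epc1 stood at 7.81 ± 0.31 and 8.09 ± 0.17 in the EPC2 knockdown of normal and leukaemic GMP, differences of 0.03 and 0.00 from the control. In the EPC1 knockdown, Epc2 differed by 0.04 in normal GMP and by 0.29 in leukaemic GMP, where it was above the control in all 3 pairs (0.51, 0.05 and 0.32).

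The exact two-sided permutation test with 3 arrays against 3 cannot give a p under 0.1. It gave 0.1 for Epc1 in both cell types and for Epc2 in leukaemic GMP, and 0.4 for Epc2 in normal GMP. Over the same-numbered pairs of both cell types, Epc1 was lower in 6 of 6 pairs after EPC1 knockdown (mean -0.43) and Epc2 in 6 of 6 after EPC2 knockdown (mean -0.41). The exact sign-flip p was 0.03125 for each, the smallest that 6 pairs allow. No target passed in limma after adjustment over all genes, and with replicate number as a block the adjusted p over both cell types was 0.0686 for Epc1 and 0.176 for Epc2.

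**Figure D1:**
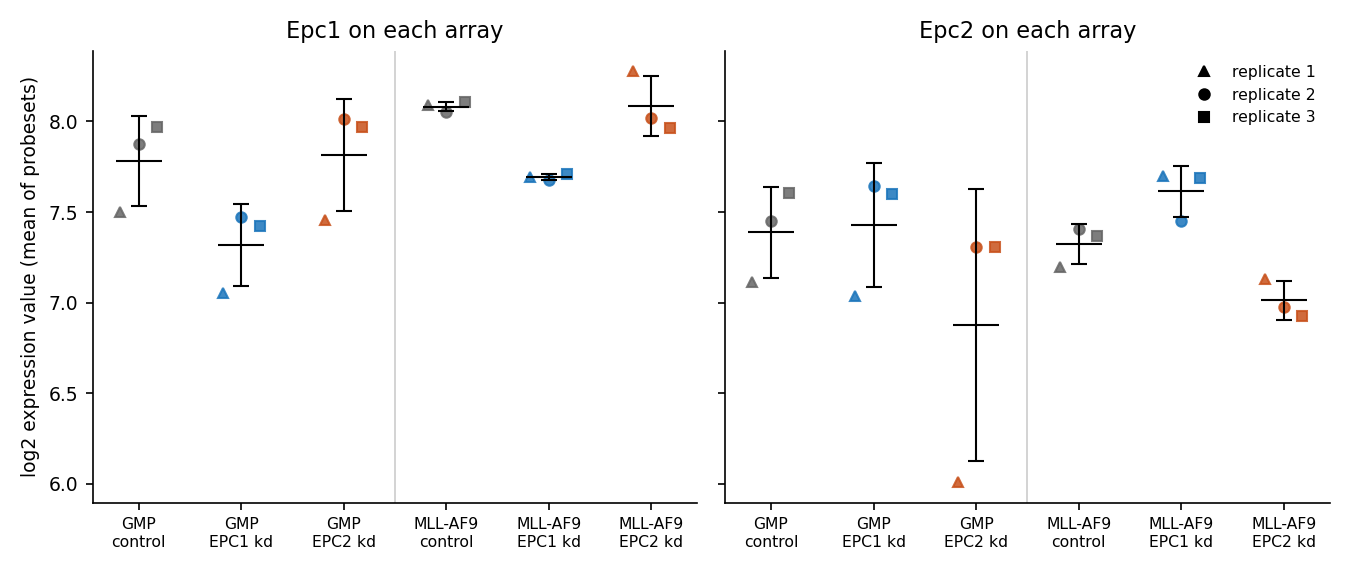
Log2 intensity of Epc1 and of Epc2 in each of the 18 arrays, by cell type and vector; points are arrays, and bars give the mean ± SD of 3 arrays. Mean Epc1 was lower after EPC1 knockdown (7.32 in normal GMP, 7.69 in leukaemic GMP) than in the controls (7.78 and 8.08), and mean Epc2 was lower after EPC2 knockdown (6.87 and 7.01) than in the controls (7.39 and 7.32).

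The first principal component held 37.5% of the variance and parted the arrays of replicate 1 from replicates 2 and 3, a split that accounted for 71.1% of its variance. The second held 27.6% and parted normal from leukaemic GMP (99.6%). Within a group, replicates 2 and 3 correlated across genes at 0.982 to 0.992, and replicate 1 with either of them at 0.907 to 0.954. Replicate number was therefore also fitted as a block, and the blocked result stands beside each comparison it changes. In leukaemic GMP, replicates 2 and 3 were not shown to be paired by number. Counts of pairs there may depend on how these arrays were matched.

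**Figure D2:**
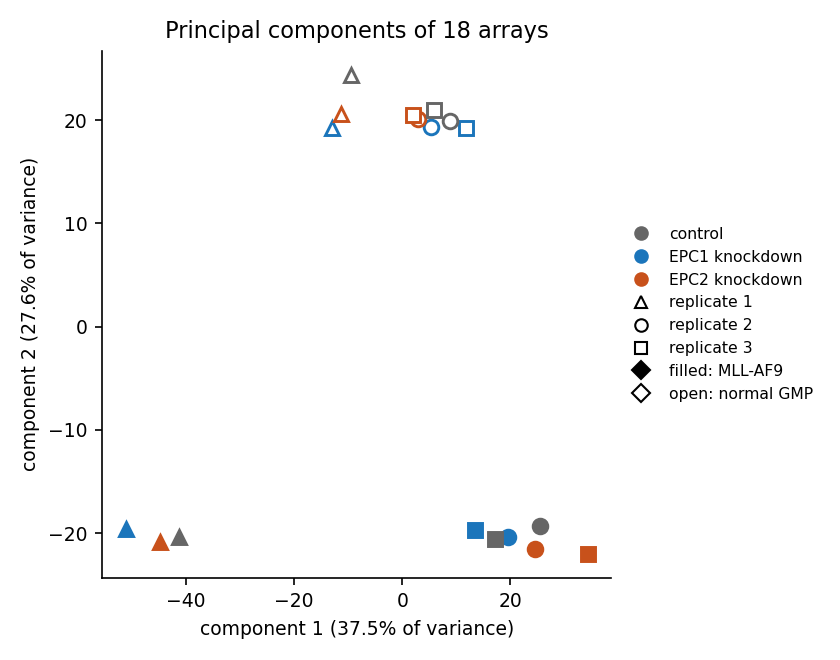
Scores of the 18 arrays on the first 2 principal components of the genes tested (37.5% and 27.6% of the variance), with colour and symbol for group and replicate. Normal and leukaemic GMP part along the second component, and the arrays of replicate 1 part from replicates 2 and 3 along the first.

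The control arrays compared leukaemic with normal GMP, both infected with the non-targeting vector and then cultured. They address how the MLL-AF9 cells differ from their normal counterpart without either knockdown. No cells taken before infection and culture were among the samples. Differences that arose in culture, such as maturation of the normal cells, therefore cannot be told apart from earlier ones. Leukaemic GMP had more signal for Hpgd, the enzyme that degrades prostaglandins (11.05 ± 0.16 against 4.72 ± 0.14, n = 3 each), and for Meis1, the homeobox cofactor of HOXA9 (8.85 ± 0.13 against 5.07 ± 0.30). Granulocyte products fell: Mmp8, the neutrophil collagenase, was 4.84 ± 0.93 in leukaemic and 9.92 ± 1.45 in normal GMP, and Ltf, lactoferrin, was 5.79 ± 0.27 and 9.41 ± 1.13. The lower level of Hpgd, Meis1 and Mmp8 lay under 5.45, the mean level that the filter asked for, so no fold is given. Here and below, differences from a mean under 5.45 are those of the deposited values, and how far background limits them was not measured. In limma, 87 genes were higher and 143 lower in leukaemic GMP.

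Targets of MLL fusions rose together (adjusted p = 7.77e-19; median 0.76). Of 23 tested, 11 rose and 12 did not pass; adjusted over the list alone, 13 rose. Besides Meis1 they included Eya1, a developmental transcriptional coactivator (3.30, SE 0.13), Pbx3, another partner of HOX proteins (2.88, SE 0.33), Hoxa5 (3.16, SE 0.55), Hoxa9 (1.98), Hoxa7 (1.32), Hoxa6 (1.33), Hoxa4 (1.09), Hoxa10 (0.76), the myeloid leukaemia factor Mef2c (1.79) and Runx2 (0.61). Other large rises were Klhl41, a muscle kelch protein (3.47, SE 0.46), Csta3, a cystatin (3.34, SE 0.49), Glyat, a glycine acyltransferase (3.17, SE 0.62), Ly6k (3.11, SE 0.32) and Igf2bp3, a fetal RNA-binding protein (3.06, SE 0.29).

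Genes of neutrophil maturation fell (adjusted p = 4.86e-21; median -1.05). Of 30 tested, 11 fell, 0 rose and 19 did not pass; adjusted over the list alone, 15 fell. Besides Mmp8 and Ltf, they included Il1r2, the interleukin 1 decoy receptor (-3.32, SE 0.47), the chitinase-like Chil3 (-3.29, SE 0.36), Anxa1 (-3.24, SE 0.63), the NADPH oxidase subunit Cybb (-3.00), Lcn2, lipocalin (-2.67), and the receptors Cxcr2 (-1.81) and Csf3r (-1.12). Eosinophil genes fell (adjusted p = 1.35e-08; median -1.24), with 2 of 5 past the threshold over all genes and 4 adjusted over the list alone. These were the granule proteins Prg2 (-3.19) and Epx, eosinophil peroxidase (-2.16). With an estimated correlation the MLL fusion targets (adjusted p = 0.00254), eosinophil genes (adjusted p = 0.00254) and neutrophil genes (adjusted p = 0.0467) kept their calls, and these were the only list calls of the 11 comparisons to do so.

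Mast cell and basophil genes fell (adjusted p = 1.01e-09; median -1.16), with adjusted p = 0.0875 with an estimated correlation. Of 13 tested, 3 fell and 7 fell adjusted over the list alone: Mcpt8, a basophil protease (-3.67, SE 0.58), Fcer1a, the IgE receptor chain (-2.54), and Slc18a2 (-0.98). Monocyte and macrophage genes fell as a list (adjusted p = 4.12e-09; median -0.56; adjusted p = 0.233 with an estimated correlation). Of 31 tested, 4 fell, 1 rose and 26 did not pass; adjusted over the list alone, 10 fell and 1 rose. Lyz2, lysozyme (-3.23), Tgfbi (-3.01), Csf2rb (-1.32) and Lyz1 (-1.01) fell, and Slpi, a secreted protease inhibitor, rose (0.82). Primary granule genes fell (adjusted p = 4.24e-08; median -0.51; adjusted p = 0.233 with an estimated correlation), with 3 of 12 past the threshold and 6 adjusted over the list alone. They were the ficolin Fcnb (-2.31), Nkg7 (-1.42) and Mpo, myeloperoxidase (-1.25). Outside the lists, Ifitm6 (-4.18, SE 0.84), the formyl peptide receptor Fpr2 (-3.69, SE 0.70), Ly6a2 (-3.48, SE 0.49) and Lpl, lipoprotein lipase (-3.42, SE 0.33), fell.

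A further 7 lists passed with few or 0 single members past the threshold. MYC targets rose (adjusted p = 0.00266; median 0.29, 48 of 55 members above 0) and so did ribosome biogenesis genes (adjusted p = 0.00523; median 0.22, 40 of 49 above 0), with adjusted p = 0.788 for each with an estimated correlation. Glycolysis and hypoxia genes fell (adjusted p = 5.86e-07; median -0.37, 26 of 28 below 0; adjusted p = 0.452 with an estimated correlation). So did genes of G2 and M phase (adjusted p = 0.000279; median -0.27, 39 of 47 below 0; adjusted p = 0.521 with an estimated correlation). The stress and unfolded protein response list fell (adjusted p = 0.000868; adjusted p = 0.631 with an estimated correlation), with the stress transcription factor Ddit3 (-0.70) as its 1 member past the threshold and 4 adjusted over the list alone. The interferon response list fell (adjusted p = 0.00228; adjusted p = 0.296 with an estimated correlation), and its 1 member past the threshold was Slfn1 (-1.40). Oxidative phosphorylation genes fell (adjusted p = 0.00973; median -0.18, 38 of 48 below 0; adjusted p = 0.817 with an estimated correlation), a call lost without replicate 2 (adjusted p = 0.112) and with quantile normalization (adjusted p = 0.0704). The sizes leaned on single replicate numbers. Without replicate 1 the median was 0.07 for MYC targets, 0.09 for ribosome biogenesis, -0.64 for neutrophil genes, -2.43 for mast cell and basophil genes, -1.08 for monocyte genes, -0.28 for the stress list and -0.30 for oxidative phosphorylation. Without replicate 2 it was -0.18 for G2 and M phase, -0.15 for the interferon response and -0.04 for oxidative phosphorylation, and without replicate 3 it was 0.34 for ribosome biogenesis.

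Lists that did not pass held single changes. The p53 target list (adjusted p = 0.0595, median 0.30) had 2 members that rose, Plk2 (0.71) and the death receptor Tnfrsf10b (0.84), and 2 that fell, Ddb2 (-0.79) and Fas (-0.88); adjusted over the list alone, 4 rose and 3 fell. Stem cell genes (adjusted p = 0.775) had Meis1 and Angpt1 (1.01) higher and Txnip (-1.02) lower. Thbs1, thrombospondin, fell (-3.01) in the megakaryocyte list (adjusted p = 0.0595), and Nfkbiz fell (-0.59) in the immediate early and NF-kB list (adjusted p = 0.0706). Cholesterol synthesis, dendritic cell and MHC class II genes and replication-dependent histones each had adjusted p = 0.0595. The adjusted p was 0.119 for autophagy and lysosome genes, 0.26 for B and T lymphoid genes, 0.285 for the NuA4/TIP60 complex, 0.603 for the MYC network, 0.634 for cytosolic ribosomal proteins and for the Polycomb group, 0.732 for erythroid genes, 0.74 for apoptosis regulators, 0.782 for proliferation brakes and 0.965 for G1/S genes. Apoptosis regulators had a median of 0.12 and a mean of 0.02 with a test direction of lower, since camera compares a list with the other genes. Epc1 (0.30, adjusted p = 0.544), Epc2 (-0.07, adjusted p = 0.953) and Myc (0.26, adjusted p = 0.739) did not pass.

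**Figure D3:**
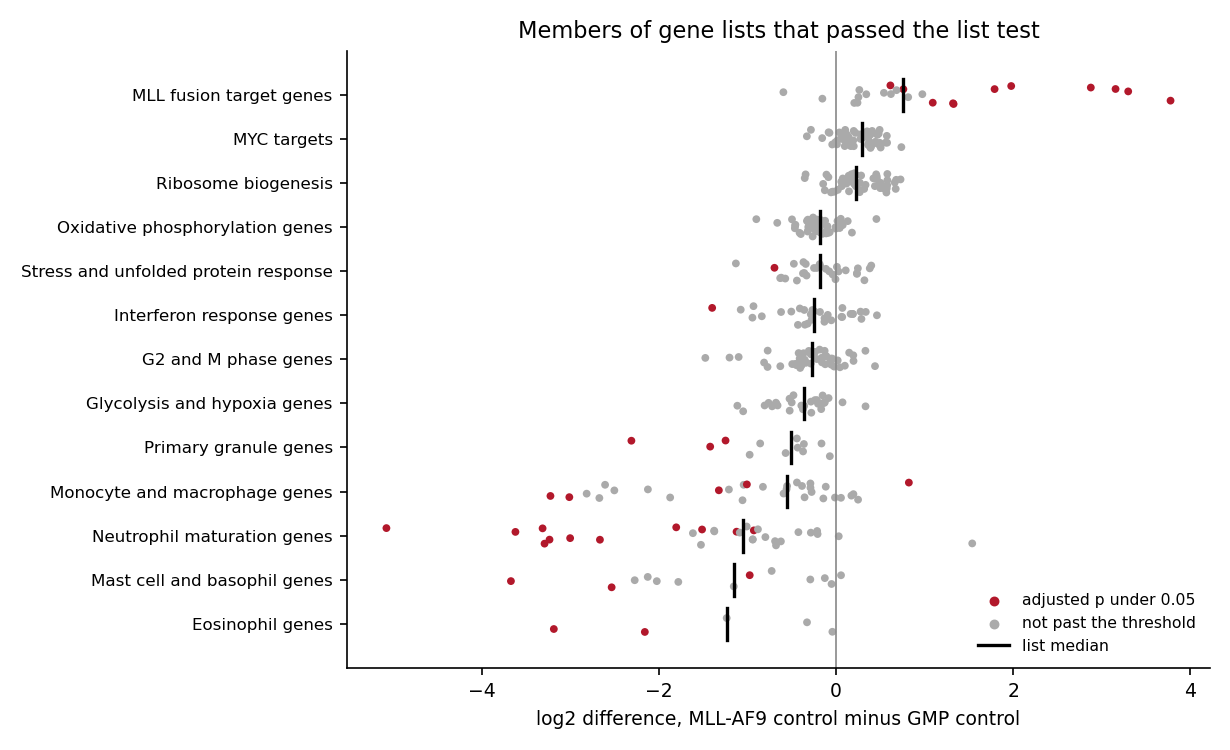
Log2 difference of leukaemic minus normal GMP in the control arrays for the tested members of the 13 lists that passed; each point is 1 gene, red marks adjusted p under 0.05 and the bar is the list's median. MLL fusion targets had a median of 0.76 and neutrophil maturation genes a median of -1.05.

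With replicate number as a block, 148 genes rose and 335 fell in the same comparison, and the 230 were among them. This block joined normal animals and separate leukaemias by number, which the labels do not pair. Replicate 2 minus 3 correlated at -0.0111 between the control arrays, so the added calls rest on a pairing not shown beyond replicate 1. The blocked fit also called cholesterol synthesis genes (adjusted p = 0.0125, lower; adjusted p = 0.662 with an estimated correlation) and histones (adjusted p = 0.000257, lower; adjusted p = 0.234 with an estimated correlation). It called dendritic cell and MHC class II genes (adjusted p = 0.0147, higher; adjusted p = 0.371 with an estimated correlation) and p53 targets (adjusted p = 0.0206, higher; adjusted p = 0.667 with an estimated correlation). Without replicate 1 the median was -0.33 for cholesterol synthesis, -0.29 for histones and 0.10 for p53 targets, without replicate 2 it was -0.04 for cholesterol synthesis, and without replicate 3 it was -0.80 for histones. Without the block, the count fell to 122 without replicate 3 of the leukaemic control, 145 without its replicate 2, 139 without replicate 3 of the normal control and 147 without its replicate 2. The blocked count fell to 303, 274, 321 and 267 without replicate 2 or 3 of the normal control and replicate 1 or 3 of the leukaemic control.

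EPC1 knockdown in normal GMP asked what a lower Epc1 level does to normal progenitors. Oxidative phosphorylation genes fell as a list (adjusted p = 0.0112; median -0.12, 35 of 48 below 0), with adjusted p = 0.999 with an estimated correlation. Genes of neutrophil maturation also fell (adjusted p = 0.0112; median -0.19, 23 of 30 below 0), again with adjusted p = 0.999 with an estimated correlation. Each list was lower in 2 of 3 pairs, and 0 members of either passed over all genes or adjusted over the list alone. The gene with the smallest p among the higher ones was Meis1 (5.86 ± 0.22 against 5.07 ± 0.30; difference 0.79, SE 0.25, with the control under 5.45), followed by Thumpd2 (0.40, SE 0.13) and the transcription factor Tfcp2 (0.50, SE 0.17). The zinc finger genes Zfp52 (-0.88, SE 0.21) and Zfp322a (-0.86, SE 0.21) and the secreted protein gene Olfml3 (-0.53, SE 0.14) had the smallest p among the lower ones. Myc, a transcription factor that recruits TIP60, differed by 0.33 (SE 0.25), with 1.13, 0.07 and -0.19 in the 3 pairs, so replicate 1 carried it.

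None of these 6 genes nor Myc passed: limma called 0 genes, with 102 at an unadjusted p under 0.05, and the blocked fit also called 0. With 3 arrays per group and Epc1 at 72.3% of the control intensity, this does not show that nothing changed. Both lists lost their calls without replicate 1, with adjusted p = 0.417 for oxidative phosphorylation and adjusted p = 0.21 for neutrophil genes (medians -0.04 and -0.08), and with quantile normalization (0.182 and 0.164). With the block both stayed (2.69e-05 and 6.31e-06), and replication-dependent histones were called lower (adjusted p = 0.0328; 7 of 7 below 0, but 2 of 3 pairs; median -0.09, and -0.05 without replicate 3; adjusted p = 0.922 with an estimated correlation).

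EPC2 knockdown in normal GMP gave no list past the threshold, with or without the block. The highest-ranked values were for Olr1, the receptor of oxidised LDL (8.60 ± 0.09 against 7.83 ± 0.14; difference 0.77, SE 0.15), the death receptor Tnfrsf10b (0.57, SE 0.15) and Saa3, an acute-phase protein (0.73, SE 0.22). Lower values stood at Gnpda1, an enzyme of amino sugar breakdown (-1.08, SE 0.30), Osbp, an oxysterol-binding protein (-0.88, SE 0.24), and the formin Fmnl1 (-0.45, SE 0.12). Gnpda1 rested on a single probeset. Myc differed by 0.23 (SE 0.25; pairs 0.53, 0.04 and 0.11). None passed over all genes: limma called 0, with 110 at an unadjusted p under 0.05, and the blocked fit called 0 (adjusted p = 0.0932 for Gnpda1, 0.0975 for Olr1 and 0.0992 for Osbp). Adjusted over the list alone, 1 of 27 p53 targets rose. Without replicate 1 of the EPC2 knockdown the blocked fit called 4 genes.

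EPC1 knockdown in leukaemic GMP asked what a lower Epc1 level does to the MLL-AF9 cells. No list passed without the block. The highest-ranked values were for Lig4, the ligase of DNA end joining (5.87 ± 0.18 against 5.28 ± 0.12; difference 0.59, SE 0.14, with the control under 5.45), Akr1e1, an aldo-keto reductase (0.57, SE 0.15), and Layn, a hyaluronan receptor (0.52, SE 0.14). Lower values stood at Zfp825 (-1.21, SE 0.32), the olfactory receptor gene Olfr642 (-0.73, SE 0.18) and Zfp322a (-0.73, SE 0.21); Zfp825 and Olfr642 rested on 1 probeset each. Myc differed by 0.22 (SE 0.25; pairs 0.15, 0.34 and 0.18).

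None of these passed: limma called 0 genes, with 173 at an unadjusted p under 0.05, and 0 with the block. With the block, genes of neutrophil maturation were called lower (adjusted p = 0.00221; median -0.15, 2 of 3 pairs, and -0.08 without replicate 3) and ribosome biogenesis genes higher (adjusted p = 0.0224; 44 of 49 above 0, 3 of 3 pairs), against adjusted p = 0.229 and 0.146 without it. With the block and an estimated correlation each had adjusted p = 0.989. In the blocked fit, 4 neutrophil genes fell and 1 rose adjusted over the list alone, and 0 passed over all genes. Without replicate 2 of the EPC1 knockdown the blocked fit called 2 genes.

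EPC2 knockdown in leukaemic GMP asked the same of Epc2. Cell cycle genes rose as lists: G1/S and S phase genes (adjusted p = 0.00468; median 0.10, 21 of 39 above 0) and genes of G2 and M phase (adjusted p = 0.00513; median 0.08, 29 of 47 above 0), both with adjusted p = 0.999 with an estimated correlation. Ribosome biogenesis genes also rose (adjusted p = 0.0474, median 0.04, 25 of 49 above 0), likewise with adjusted p = 0.999 with an estimated correlation. Camera compares a list with the other genes, and the median of all tested genes was -0.05 here, so these rises are relative. Each of the 3 lists was higher in 2 of 3 pairs, and 0 of their members passed over all genes or adjusted over the list alone. With the block 9 genes were called, 3 higher and 6 lower. Clock, the circadian transcription factor, rose (0.75, SE 0.13 with the block). Those that fell included Npc2, a lysosomal cholesterol carrier (-1.30, SE 0.20), Rbbp4, a histone chaperone shared by several chromatin complexes (-1.03, SE 0.14), the motor protein Myo1g (-0.89, SE 0.12) and Fam98b (-0.79, SE 0.12). Further values that did not pass were Olr1 (0.62), the chaperone gene Anp32b (0.47), Ifitm7 (0.47), the kinase subunit Phkg2 (-0.69), the GTPase Ralb (-0.71) and Arhgap1 (-0.73). Myc differed by 0.21 (SE 0.25; pairs 0.21, 0.65 and -0.24).

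Without the block limma called 0 genes here, with 253 at an unadjusted p under 0.05 (adjusted p = 0.113 for Rbbp4). The blocked count was 1 without replicate 1 of the EPC2 knockdown, 3 without replicate 2 of the control and 0 without any other single array of these groups. Without replicate 1 the list medians turned to -0.05 for G1/S, -0.01 for G2 and M phase and -0.04 for ribosome biogenesis genes (-0.02 without replicate 2). Without replicate 1, G1/S genes had adjusted p = 0.102 and ribosome biogenesis genes 0.154, and the latter 0.181 without replicate 2 and 0.0699 with no filter. With quantile normalization G2 and M phase genes had adjusted p = 0.209 and ribosome biogenesis genes 0.256. The blocked fit also called 5 lists lower: autophagy and lysosome genes (adjusted p = 0.0103), stress and unfolded protein response genes (0.0284), monocyte genes (0.034), neutrophil genes (0.00347) and primary granule genes (0.0026). Replicate 3 carried most of these falls: its pair had medians of -0.39, -0.37, -0.35, -0.40 and -0.59 in that order, and without it the medians were -0.06, 0.02, -0.07, -0.12 and -0.05. The stress and neutrophil lists were lower in 3 of 3 pairs and the other 3 lists in 2. The blocked fit called the Polycomb group higher (adjusted p = 0.034; median 0.03, and -0.04 without replicate 1). With the block and an estimated correlation all of these had adjusted p = 0.908.

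The direct comparison of the vectors in normal GMP asked where EPC1 and EPC2 knockdown part. Oxidative phosphorylation genes were lower after EPC1 than after EPC2 knockdown (adjusted p = 0.00363; median -0.16, 38 of 48 below 0, 3 of 3 pairs), with adjusted p = 0.963 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone. With the block 7 genes were higher and 9 lower after EPC1 knockdown. Higher were Gfus, an enzyme of GDP-fucose synthesis (1.17, SE 0.20), Osbp (1.15, SE 0.17), Fam98b (0.98, SE 0.12), the protein kinase A subunit Prkar2a (0.88, SE 0.15), Rcn1 (0.72), Myo1g (0.69) and the urokinase gene Plau (0.68). Lower were Zfp322a (-1.01, SE 0.15), Septin10 (-0.79), the ubiquitin ligase gene Wwp1 (-0.79), Svbp (-0.72), Dpy30, a core subunit of MLL-type methyltransferases (-0.64, SE 0.11), and Cstdc4 (-3.19) and Cebpzos (-0.91), which rested on 1 probeset each. Values that did not pass were Fmnl1 (0.52), Arnt (0.61), Rbbp4 (0.58), Zfp943 (-0.72), Olr1 (-0.61) and Zfp52 (-0.79), beside Epc1 (-0.50), Epc2 (0.55) and Myc (0.11).

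Without the block limma called 0 genes, with 226 at an unadjusted p under 0.05. The blocked count was 3 or 5 without replicate 1 or 3 of the EPC1 knockdown, and 5, 4 or 2 without replicate 1, 2 or 3 of the EPC2 knockdown. The oxidative phosphorylation call was lost without replicate 1 (adjusted p = 0.142, median -0.10) and with quantile normalization (adjusted p = 0.128). With the block it stayed (1.31e-06), and cytosolic ribosomal proteins (adjusted p = 0.0384) and histones (adjusted p = 0.0017) were called lower, with adjusted p = 0.972 for all 3 with the block and an estimated correlation.

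In leukaemic GMP, p53 target genes were higher after EPC1 than after EPC2 knockdown (adjusted p = 8.75e-05; median 0.28, 24 of 27 above 0, 3 of 3 pairs), with adjusted p = 0.996 with an estimated correlation. No member passed over all genes, and 0 adjusted over the list alone (5 with the block). Values of members that did not pass over all genes included Ccng1 (0.44), Trp53inp1 (0.59), and, picked after their values were seen, Cdkn1a (0.45) and Mdm2 (0.28). All tested genes had a median difference of 0.09 in this comparison, and of -0.01 with quantile normalization, where the p53 targets had a median of 0.18. With the block 47 genes were higher and 8 lower after EPC1 knockdown. How far the offset of all genes accounts for this lean was not tested. Higher were Npc2 (1.28, SE 0.20), the mitochondrial ribosomal protein gene Mrps25 (1.21, SE 0.14), Rbbp4 (1.10, SE 0.14), Gfus (1.07, SE 0.20), Cmc1, a mitochondrial assembly factor (0.98, SE 0.13), Far2 (0.96), Fam98b (0.95), the antiproliferative gene Btg3 (0.88), Osbp (0.86) and Myo1g (0.80). Lower were Zfp322a (-0.97, SE 0.15), the calcium pump gene Atp2b1 (-0.94, SE 0.13), Olfr642 (-0.85), Thbs1 (-0.78), Rab2b (-0.76) and Gca (-0.71). Among list members, the macrophage genes Ms4a6b (1.30) and Adgre1, which encodes F4/80 (0.88), the autophagy gene Atg5 (0.90), the proton pump gene Atp6v0d1 (0.69) and the B cell receptor gene Cd79b (0.70) were higher. Values that did not pass were Kit (-0.57), Olr1 (-0.52) and Cldn3 (-0.33), beside Epc1 (-0.39), Epc2 (0.60) and Myc (0.02).

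Without the block limma called 0 genes, with 248 at an unadjusted p under 0.05 (adjusted p = 0.0526 for Rbbp4). The blocked count was 6 or 4 without replicate 2 or 3 of the EPC1 knockdown, 8, 6 or 13 without replicate 1, 2 or 3 of the EPC2 knockdown and 0 without replicate 1 of the EPC1 knockdown. The blocked fit called 6 further lists higher after EPC1 knockdown: interferon response (adjusted p = 0.0106), primary granule genes (0.00911), glycolysis and hypoxia (0.0294), oxidative phosphorylation (0.0358), monocyte genes (0.0419) and stress and unfolded protein response (0.0488). Oxidative phosphorylation (pairs 0.06, -0.02 and 0.46) and primary granule genes (0.20, -0.01 and 0.52) were higher in 2 of 3 pairs, and replicate 3 carried them: without it the medians were 0.02 and 0.12, and the test of oxidative phosphorylation turned direction. For the stress list the median was 0.11 without replicate 3. G2 and M phase genes were called lower (adjusted p = 0.0011) with pairs of -0.12, -0.20 and 0.22, a median of 0.04 without replicate 2 and the opposite direction with fry. With the block and an estimated correlation, oxidative phosphorylation had adjusted p = 0.947, p53 targets 0.701 and the others 0.913.

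The difference of the knockdown effects between leukaemic and normal GMP asked whether leukaemic cells respond in another way. The EPC1 effect on oxidative phosphorylation genes lay higher in leukaemic than in normal GMP (adjusted p = 0.0112; median difference 0.24, 39 of 48 above 0), with adjusted p = 0.992 with an estimated correlation. The EPC2 effect lay higher in leukaemic GMP for G1/S and S phase genes (adjusted p = 0.0345; median 0.07) and for genes of G2 and M phase (adjusted p = 0.0345; median 0.09), both with adjusted p = 0.97 with an estimated correlation. No member of the 3 lists passed over all genes or adjusted over the list alone. The largest-ranked values for EPC1 were Olfml3 (0.62, SE 0.20), the nicotinic acid receptor gene Hcar2 (0.63, SE 0.24) and Xpnpep3 (0.72, SE 0.28), and Olfr642 (-0.98, SE 0.26), Fam131c (-0.59, SE 0.16) and the transcription factor gene Twist1 (-0.77, SE 0.22). For EPC2 they were Ifitm7 (0.80, SE 0.18), Anp32b (0.53, SE 0.18) and the keratin gene Krt8 (0.74, SE 0.27), and Tnfrsf10b (-0.83, SE 0.21), Zfp708 (-1.07, SE 0.30) and Pias3 (-0.60, SE 0.17).

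None of these 12 genes passed: limma called 0 for the EPC1 difference, with 109 at an unadjusted p under 0.05, and 0 for the EPC2 difference, with 115, and the blocked fit called 0 for both. Adjusted over the list alone, 1 p53 target fell in the EPC2 difference. The oxidative phosphorylation call was lost without replicate 2 (adjusted p = 0.0643) and the cell cycle calls without replicate 1 (0.777; medians -0.13 for G1/S and -0.11 for G2 and M phase) or 2 (0.0681) or with no filter (0.0998), and quantile normalization ended all 3 (0.216, 0.287 and 0.288). The blocked fit added histones, higher in the EPC1 difference (adjusted p = 0.0293; adjusted p = 0.997 with an estimated correlation; median 0.36, and 0.18 without replicate 1), and monocyte genes, lower in the EPC2 difference (adjusted p = 0.0201; adjusted p = 0.979 with an estimated correlation; median -0.22, and -0.06 without replicate 3).

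EPC1 knockdown called 0 genes in either cell type, with or without the block, so no overlap of calls with EPC2 knockdown could arise. Across genes, which are not independent replicates, the EPC1 and EPC2 effects correlated at 0.196 in normal GMP and 0.507 in leukaemic GMP. Unchanged groups simulated against shared controls gave a mean of 0.504 and a range of -0.227 to 0.945. The covariance was 0.00576 in normal and 0.0172 in leukaemic GMP, against a simulated mean of 0.0114 (-0.00155 to 0.0355). Effects had the same sign for 57.5% and 64.4% of genes, against 67.9% in the simulation. The correlations and covariances lay within these ranges, so no excess over shared controls was shown. The ranges are wide, so an effect common to both vectors is not excluded either. Between cell types, which share no arrays, the EPC2 effects correlated at 0.268 and the EPC1 effects at 0.119 across genes, and unchanged groups gave -0.706 to 0.743.

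The mean effect of each vector over both cell types was compared after the data had been seen. EPC2 knockdown with the block gave 16 genes that rose and 36 that fell. The metal-binding metallothionein gene Mt2 (1.12, SE 0.20), the ubiquitin ligase gene Ube3c (0.89, SE 0.10), Rab2b (0.81, SE 0.11), Olr1 (0.70, SE 0.10), Septin10 (0.66), Il6st, the shared receptor chain of the interleukin 6 family (0.63), Tmem184c (0.62), Clock (0.61), Twf1 (0.57) and Kpna3 (0.52) rose. Npc2 (-1.08, SE 0.14), Mrps25 (-0.91, SE 0.10), Osbp (-0.89, SE 0.12), Gfus (-0.86, SE 0.14), Myo1g (-0.78, SE 0.09), Gnpda1 (-0.72), Prkar2a (-0.71), the interferon-induced scramblase gene Plscr1 (-0.70), Idh3a, a subunit of the citric acid cycle enzyme isocitrate dehydrogenase (-0.69), and Fam98b (-0.67) fell. Among list members, the p53 targets Trp53inp1 (-0.65) and Ccng1 (-0.60), the neutrophil receptor gene Cxcr2 (-0.50), Adgre1 (-0.47) and Cd79b (-0.44) fell and Angpt1, a ligand of the TIE2 receptor (0.46), rose. Of the 52 genes, 50 had the same sign in all 6 pairs, and 33 fell by more than Epc2 itself. The genes were picked by a fit on these same pairs, so both counts follow largely from the selection.

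EPC1 knockdown over both cell types with the block gave 2 genes that rose, Tmem184c (0.77, SE 0.09) and Ube3c (0.69, SE 0.10), both also among the 52, and 3 that fell: Zfp322a (-0.80, SE 0.11), Fgl2, a fibrinogen-like protein of immune cells (-0.63, SE 0.10), and Sptssa, a subunit of the first enzyme of sphingolipid synthesis (-0.55, SE 0.08). Without the block neutrophil maturation genes fell (adjusted p = 0.00487; median -0.13) and ribosome biogenesis genes (adjusted p = 0.0144; median 0.13) and the Polycomb group (adjusted p = 0.0314; median 0.13) rose, each with adjusted p = 0.906 with an estimated correlation. Values that did not pass were Mansc1 (0.48), Akr1e1 (0.37), Lig4 (0.35), Zfp825 (-0.88), Zfp52 (-0.76) and Chrm2 (-0.67), beside Myc (0.28 for EPC1 and 0.22 for EPC2).

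**Figure D4:**
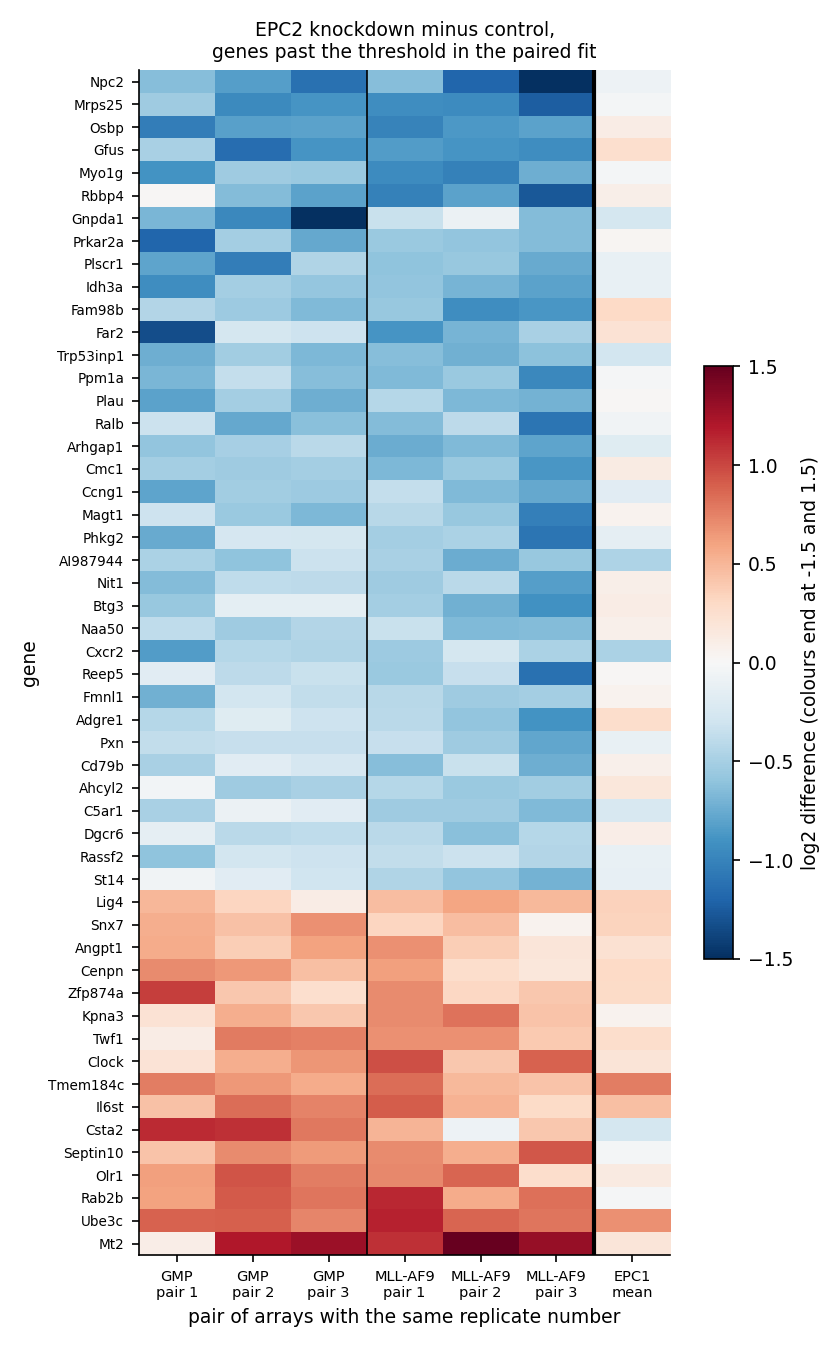
Log2 difference of EPC2 knockdown minus control for the 52 genes called over both cell types, in each of the 6 same-numbered pairs, with the mean EPC1 difference in the last column; colours end at -1.5 and 1.5. Of the 52 genes 16 rose and 36 fell, and 50 had the same sign in all 6 pairs, which were also the pairs used to pick them.

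Without the block limma called 0 genes for either vector over both cell types, with 260 at an unadjusted p under 0.05 for EPC2 and 193 for EPC1. The 52 became 33 or 27 without replicate 2 or 3 of the normal control, 31 or 28 without replicate 1 or 3 of the leukaemic control and 32 without replicate 1 or 3 of the leukaemic EPC2 knockdown. The EPC1 count of 5 became 2 without replicate 1 of either control or replicate 3 of the leukaemic EPC1 knockdown, 3 without replicate 3 of the normal EPC1 knockdown, 8 without its replicate 2, 1 without replicate 2 or 3 of the leukaemic control and 0 without replicate 1 of the leukaemic EPC1 knockdown. The list calls for EPC1 were lost with quantile normalization (0.0591 for neutrophil and ribosome biogenesis genes and 0.0787 for the Polycomb group), and without replicate 3 ribosome biogenesis genes had adjusted p = 0.111 and the Polycomb group 0.116, the latter 0.239 without replicate 1 (median 0.06) and 0.0631 with RNA input as a covariate. For EPC2 the blocked fit called neutrophil and primary granule genes (adjusted p = 0.00161 each), autophagy and lysosome genes (0.0282) and stress and unfolded protein response genes (0.0274) lower, and G1/S genes (0.0285) and genes of G2 and M phase (0.0274) higher, with adjusted p = 0.901 for all 6 with an estimated correlation. Without replicate 3 the medians were -0.07 for primary granule, -0.03 for autophagy and -0.01 for stress genes, and without replicate 2 they were -0.01 for G1/S and 0.01 for G2 and M phase genes.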

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

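The counts over other splits of the arrays and the tests of explanations below were chosen after the results were seen; the tests of the differences between cell types were planned.

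The difference between leukaemic and normal GMP itself passed for 3 lists and stood out, untested, for 2 genes. The EPC1 effect on oxidative phosphorylation genes was higher in leukaemic GMP (adjusted p = 0.0112, median 0.24), with adjusted p = 0.992 with an estimated correlation. The EPC2 effect was higher in leukaemic GMP for G1/S and S phase genes (adjusted p = 0.0345, median 0.07) and for genes of G2 and M phase (adjusted p = 0.0345, median 0.09), with adjusted p = 0.97 for both with an estimated correlation. Without replicate 1 these 2 medians turned to -0.13 and -0.11. Both EPC2 calls were lost without replicate 1 or 2 and with no filter, and the EPC1 call without replicate 2. Quantile normalization ended all 3. Ifitm7, an interferon-induced membrane protein gene, was higher than the control in all 3 leukaemic pairs of EPC2 knockdown and lower in all 3 normal pairs (difference 0.80), and Tnfrsf10b moved the opposite way (-0.83); these genes were picked because every pair was opposite, so that difference was not tested beyond limma, where neither passed (adjusted p = 0.961 with the block).

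The arrays of replicate 1 stood apart from replicates 2 and 3 in every group. Lower RNA input is one candidate explanation: it would shift the same genes in all groups, and the shifts of replicate 1 correlated across genes at 0.248 at the least and 0.920 at the most, with 0.248 to 0.381 between cell types. Separate preparation of each replicate number is another: the median correlation between groups of replicate 2 minus 3 was 0.0779. Input and preparation cannot be told apart, because the same arrays had the lower input and the number 1. The replicates were also separate animals or separate leukaemias, and a difference between these stays open, untested.

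For the 52 genes called for EPC2 knockdown over both cell types, exchanging labels within the 6 pairs gave at most 6 genes in any other exchange. Only 1 of 32 exchanges, the real one, reached 52, which is the smallest share that 6 pairs allow. Both the comparison and this count were chosen after the data were seen, and without the block 0 genes were called. Chance is therefore less likely for the blocked count but is not excluded. With replicates 2 and 3 alone, 40 of the 52 were called in the same direction, so these calls did not need the arrays read as low-input. The 52 were picked with the same arrays of replicates 2 and 3, so this is no independent support for the genes. The values argue against control arrays that stand apart as the whole cause. In the EPC1 knockdown, along the EPC2 direction, the 36 lower genes shifted by a median of 0.00296. The 16 higher genes shifted by 0.248 (upper quartile 0.34), and the median over the 52 in the EPC2 knockdown was 0.61. For the higher genes a part stays open, and Tmem184c and Ube3c were called for EPC1 too. Fewer monocytic cells stay open as a cause. The 31 tested monocyte genes had a median of -0.0805 (quartiles -0.17 and 0.08). The 5 most abundant ones did not pass (Slpi -0.06, Ctsd -0.19, Lyz2 0.03, Ctsb -0.07, Csf2rb -0.17). The median of -0.61 for the 36 genes that fell cannot be set against this, because those genes were picked for falling. Adgre1 (-0.47) is among the 52, and the blocked fit called the monocyte list lower for EPC2 in leukaemic GMP (adjusted p = 0.034). That call did not hold with an estimated correlation, and its median of -0.21 was -0.07 without replicate 3. Still open, and untested, are further transcripts hit by the EPC2 vector, whose sequence was not used here, and a lower level of EPC2 itself. No further vector against Epc2 and no rescue is among the samples.

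For the EPC1 count over both cell types with the block, the real labels gave 5 genes and the highest other exchange gave 1. The share of 1 of 32 is again the smallest possible, and the comparison was added later. Leaving out single arrays took this blocked count down to 0, so chance stays open. For the counts of 0 without the block the splits say nothing about chance, because every split reaches 0: 100 of 100 drawn splits did for each of the EPC1 and EPC2 differences and the means over both cell types (highest others 1, 0, 1 and 0). The 10 splits of 3 arrays against 3 are too few to give a share under 0.05. The leukaemic against normal controls gave 230 genes and 0 in the highest other split (1 of 10), and the knockdown comparisons and the comparisons of the vectors gave 0, which all 10 of 10 reach whatever the arrays hold, with 1 in the highest other split for EPC1 in leukaemic GMP and 0 for the others. The 4 exchanges within 3 pairs are likewise too few: the real counts were 9, 16, 55 and 483 for EPC2 in leukaemic GMP, the vectors in normal and in leukaemic GMP and the controls, each reached by 1 of 4, with 0 in the highest other.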

How the results depend on the processing

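The replicate 1 covariate, the arrays of replicates 2 and 3 alone, the combinations with the block and both comparisons over the 2 cell types were chosen after seeing the data; the other alternatives were planned. With replicate number as a block, counts rose from 0 to 9 for EPC2 in leukaemic GMP, 16 and 55 for EPC1 against EPC2 in normal and leukaemic GMP, 5 and 52 for EPC1 and EPC2 over both cell types, and from 230 to 483 for leukaemic against normal controls, and list calls over the 9 planned comparisons from 23 to 47; beside these and the lists named with it, the block changed no other call. RNA input as a covariate gave 1, 3 (leukaemic EPC1 against EPC2), 9 (EPC2 over both; 1 higher, 8 lower) and 561 (controls), and 41 lists over the planned comparisons. The replicate 1 covariate gave 15 and 33 for EPC2 in normal and leukaemic GMP, 25 (7 higher, 18 lower) and 100 for EPC1 against EPC2, 9 and 80 over both cell types and 1725 for the controls. Replicates 2 and 3 alone gave 3, 54 (5 higher, 49 lower), 8, 148, 3, 95 and 1552 (310 higher, 1242 lower) in the same order. Quantile normalization gave 2 and 3 for EPC1 against EPC2, 1 and 14 over both cell types and 425 for the controls. The control count was 139 with the stricter filter, which tests fewer genes, and 99 with only the compared arrays, which leave fewer degrees of freedom; it was 278 with no filter, 227 with a trend and robust prior and 243 with the gene-level table. The causes of the other shifts were not tested. Leaving out single arrays, with and without the block, gave 0 to 4 for EPC2 in normal GMP, 0 to 2 and 0 to 3 for EPC1 and EPC2 in leukaemic GMP, 0 to 19 and 0 to 13 for EPC1 against EPC2, 122 to 342 for the controls, 0 to 8 and 0 to 70 over both cell types, and 0 throughout for EPC1 in normal GMP and the differences. The highest of these came without replicate 2 of the leukaemic control (342, with the block) and replicate 1 of the normal EPC2 knockdown (70, with the block), and the lowest control count without replicate 3 of the leukaemic control (122); without the block, EPC2 over both cell types gave 5 without replicate 1 of the leukaemic EPC2 knockdown and 1 without replicate 1 of the normal one. Of the 23 list calls of the 9 planned comparisons, 3 held with an estimated correlation. Fry gave 5, all for the controls, and 4 of them were among the 13 lists camera had called there. The block gave 3 with an estimated correlation and 10 with fry. Of these 10, 9 were for the controls, with 6 among the 13. In the same 9, leaving out a replicate number gave 27 to 36 lists and no filter 30. These totals include lists that were not among the 23. For EPC2 in leukaemic GMP without replicate 1, for example, 5 lists were called and 1 of the 3 was kept. Without a replicate number, list medians turned sign as given for EPC2 in leukaemic GMP and for the EPC2 difference, and for the blocked calls of the stress list (0.02 without replicate 3) and the Polycomb group (-0.04 without replicate 1) for EPC2 in leukaemic GMP, of G2 and M phase genes between the vectors there (0.04 without replicate 2) and of G1/S genes for EPC2 over both cell types (-0.01 without replicate 2). Other values turned sign for Myc, GMP EPC1 knockdown against control (-0.0612 with replicates 2 and 3 alone), for G2 and M phase genes between the vectors in leukaemic GMP (adjusted p = 0.998 with fry) and for oxidative phosphorylation genes there (adjusted p = 0.0614 to 0.853 without single replicate numbers, the turn without replicate 3); the cause was not tested. Quantile normalization left the direction of every list called with or without the block as it was and moved the median of all genes by at most 0.09. Averaging the probesets of a symbol was already the setting used, so the brightest probeset was not run as a second choice. Where leaving out an array left a group with 2, limma's pooled spread was used. Signal over background cannot be given from these values. Genes with a mean near the floor were removed by the filter and tested only in the alternative with no filter.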

Other observations

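The list tests here were planned; the pooled comparison and the picks of single genes were chosen after the results were seen.

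The NuA4/TIP60 complex, to which both targets belong, and the Polycomb group were followed through the knockdowns. The 18 genes of the complex had medians of 0.09 and 0.17 after EPC1 knockdown in normal and leukaemic GMP and 0.03 and 0.02 after EPC2 knockdown (adjusted p = 0.923, 0.229, 0.984 and 0.173). In normal GMP the test pointed lower after both knockdowns while median and mean lay above 0. The 27 Polycomb genes had medians of 0.15 and 0.13 after EPC1 knockdown (adjusted p = 0.0977 and 0.229) and -0.03 and 0.03 after EPC2 knockdown (adjusted p = 0.943 and 0.0686), with a mean of 0.04 and a test direction of higher beside the median of -0.03.

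MLL fusion targets, the list with the largest rise in leukaemic GMP, passed in no knockdown: medians were 0.12 and 0.04 after EPC1 and EPC2 knockdown in leukaemic GMP (adjusted p = 0.282 and 0.268) and 0.13 and 0.06 in normal GMP (adjusted p = 0.576 and 0.943; the last with a test direction of lower). MYC targets had medians of 0.10 and -0.09 after EPC1 and EPC2 knockdown in leukaemic GMP (adjusted p = 0.292 and 0.74). In normal GMP their medians were 0.11 and 0.03 (adjusted p = 0.4 and 0.943). Their rise in leukaemic against normal GMP was lost with an estimated correlation, and its median was 0.07 without replicate 1. The 17 stem cell genes stood highest after EPC1 knockdown in normal GMP (median 0.12, 15 above 0, adjusted p = 0.0894). Megakaryocyte, lymphoid, erythroid, NuA4/TIP60, apoptosis, MYC network, proliferation brake, stem cell and immediate early lists passed in none of the 11 comparisons, with or without the block.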
